A study of Xenopus tropicalis with 4 samples.

How the data were processed

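The series holds 4 libraries from whole *Xenopus tropicalis* embryos, 1 for each of H3K4me3 ChIP-seq, H3K27me3 ChIP-seq, RNAPII ChIP-seq and RNA-seq. Per the labels, chromatin came from 300 to 600 embryos of stages 11 to 12, and RNA from stages 10 to 13. Groups were taken from the antibody labels and, for RNA, from the sample title. The labels list 5 raw files for each histone library, 2 for RNAPII and 9 for RNA, so each deposited file appears to combine several sequencing runs. The runs were not analysed here separately, and input DNA was not analysed here.

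The authors deposited mapped reads as intervals on the scaffolds of JGI version 4.1, described in the accompanying text as filtered unique reads of 32 bp. Entries of both histone libraries are 133 bp long and those of RNAPII and RNA 32 bp. The authors deposited lists of enriched regions for H3K4me3 and H3K27me3, found with a sliding window per the accompanying text. Its threshold, and the aligner, are not given in the sources used here. Per the file headers, the authors' expression table gives for each JGI FilteredModels version 1 gene model the count of RNA reads and a ratio of that count to the number of possible unique reads of 32 bp. This ratio is not scaled to depth. The deposited ratio differed from the quotient of the other columns by at most 0.493%.

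Reads were assigned to regions by the middle of the entry. Density was computed as reads per kb and per 1000000 deposited reads of the library (RPKM). Background density was taken over all sequence outside both lists, with scaffold lengths bounded below by the last entry in any file, 1455.94 Mb in 16670 scaffolds. An H3K4me3 or H3K27me3 region was called shared when it overlapped the other list by at least 1 bp, and otherwise H3K4me3-only or H3K27me3-only. RNA of a region was counted in the region and 5 kb either side, and its density divided by that full span even where it ran past a scaffold end, as for 16.3% of H3K27me3-only, 3.75% of shared H3K4me3 and 4.91% of H3K4me3-only regions. Log2 values of regions used a pseudocount of 0.1 RPKM, those of gene models 0.01 on the deposited ratio, and those of RNA entries per kb of scaffold 1. Exact Clopper-Pearson intervals were used for shares, exact Poisson intervals for read totals, order statistics for medians, 1000 bootstrap draws over regions for mean differences and 200 for rho, all at 95%. PCR and sequencing copies carried no molecular identifiers, so intervals cover counting error only.

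Random placement kept each H3K27me3 region's width and scaffold and was drawn 1000 times. Random region sets were drawn 10000 times, either from all regions or matched on 10 equal groups of RNA density, and the class median's percentile among them is a description of these libraries. For these sets H3K4me3-only, shared H3K4me3 and H3K27me3-only regions were pooled. No p-values across regions or genes were computed. The design written before the data were examined placed classes on gene 5′ ends. The files hold no gene coordinates on this build, and 0 of 26890 model identifiers matched the gene name table used here, so the design's stated fallback was followed and RNA and RNAPII were measured in regions instead. For the same reason the 10 gene lists fixed beforehand (mesendoderm and organizer genes, ectoderm and neural plate genes, Hox genes, later developmental regulators, differentiated-cell genes, ribosomal protein genes, cell maintenance genes, oocyte and germ plasm genes, Polycomb and Trithorax group genes, cell division genes) could not be classed, and no gene is named.

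Items named in the text follow a rule fixed before the data were examined. It took the 10 widest regions of each mark and the 10 longest overlaps, by scaffold and position where no gene name is given. It also took the 5 genes highest in RNA of each class and, among genes with H3K27me3, the 10 highest in RNAPII. As genes could not be placed, these became regions ranked by RNA with 5 kb either side and H3K27me3 regions ranked by RNAPII. The few items that matter are described in full. Windows in the closing section were chosen after their values were seen. Scaffold numbers in model identifiers were checked on 744 scaffolds with at least 10 models, where reads per model in the table and RNA entries per model on the scaffold had a rho of 0.934, against -0.0161 after shuffling. Single-model classes are presence of a region on the scaffold, not at a promoter.

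The depth per library sets the precision. A 10-kb window had a median of 4 H3K4me3, 8 H3K27me3, 30 RNAPII and 1 RNA reads. Different start positions made up 99.2% of H3K4me3, 98.5% of H3K27me3 and 98.1% of RNAPII reads, with at most 2 reads per start, and 32.7% of RNA reads, with up to 3140 per start. Extension of entries placed 410 H3K4me3 and 863 H3K27me3 starts before the first base of a scaffold.

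Alternatives set before the data were examined were other overlap rules, the upper 50% of each list by density, 1 read per start, scaling to reads outside both lists, other pseudocounts and a floor on RNA, here 10 reads. Counting starts 1 bp apart as 1 read, a local background, other flanks and windows, flanks ending at the scaffold's ends, scaffolds of at least 10 kb and, in place of reads per kb of gene span, RNA entries per kb of scaffold were added after the data were seen, as was the use of the floor for rho within shared, H3K27me3 and H3K27me3-only regions. On simulated data, overlap pairs were recovered for 100% of 2400 regions, 200 regions planted among 600 gave 0.960 of the overlapping regions sought, density folds of 2 and 4 planted in 200 of 12281 regions came back as 2.06 and 3.97, and random sets put a class drawn like the rest at percentile 88.7 and a class raised 1.5-fold at 100. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.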

Results

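Chromatin and RNA of whole gastrulae of the frog *Xenopus tropicalis* were profiled in 4 libraries, 1 per assay. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on embryos of stages 11 to 12 with antibodies to H3K4me3, a histone mark found at promoters of active genes, to H3K27me3, the histone mark laid down by Polycomb repressive complexes, and to RNA polymerase II (RNAPII). RNA sequencing (RNA-seq) covered stages 10 to 13. The deposited reads numbered 1528949 for H3K4me3, 2218926 for H3K27me3, 8244269 for RNAPII and 20909349 for RNA. With 1 library per assay there was no replicate spread, and all intervals below are 95% intervals that cover counting error or the spread across regions only. In the H3K4me3 and H3K27me3 libraries, 34.8% and 31.6% of read starts had a partner 1 bp on, and counting intervals are too narrow where such pairs are copies. Read densities are reads per kb and per 1000000 deposited reads of the library (RPKM), and positions are on the JGI 4.1 scaffolds.

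The first comparison asked where the 2 histone marks lie. H3K4me3 regions were numerous and narrow, while H3K27me3 regions were fewer and included very broad ones. The 12281 H3K4me3 regions covered 30.8 Mb with a median width of 2100 bp, and the widest measured 19.6 kb. The 3599 H3K27me3 regions covered 16.4 Mb with a median width of 2650 bp, and the widest measured 131.65 kb. H3K27me3 regions of at least 10 kb numbered 297, 8.25% of the list, and held 38.8% of its covered length, against 18 H3K4me3 regions (0.147%) with 0.716% of the length.

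Broad H3K27me3 regions were also the most densely marked. Median H3K27me3 density was 6.01 RPKM in the 1226 regions under 2 kb, 10.8 RPKM in the 473 regions of 5 to 10 kb and 49.8 RPKM in the 122 regions of 20 kb or more, and this last group alone held 50.1% of the H3K27me3 reads inside regions. Across all H3K27me3 regions, width and density had a Spearman rho of 0.444 (0.413 to 0.469). H3K4me3 regions held 55.6% of the H3K4me3 reads (55.5 to 55.7%, exact Clopper-Pearson), and H3K27me3 regions held 39.7% of the H3K27me3 reads (39.6 to 39.8%). RNAPII reads fell into H3K4me3 regions for 18.3% of the library and into H3K27me3 regions for 3.04%.

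The next comparison asked how often both marks occupy the same sequence in embryos of this stage. About as many H3K27me3 regions overlapped an H3K4me3 region as did not: 1861 of 3599 did by at least 1 bp (51.7%, 50.1 to 53.4%), and 1780 (49.5%, 47.8 to 51.1%) when the overlap had to cover at least 0.5 of the narrower region. At 1 bp, the overlap took in 2025 of 12281 H3K4me3 regions (16.5%, 15.8 to 17.2%). When H3K27me3 regions were placed at random on their own scaffolds 1000 times, a mean of 274 and a maximum of 320 overlapped H3K4me3, so the observed number was 6.78 times the random mean. Placement could fall on any sequence, including gaps and unmappable sequence where no region can be called, so ratios to it are raised by an unknown factor. They do not by themselves show a link between the marks. In the upper 50% of each list by density the marks still met more often than at random, with 351 of 1801 H3K27me3 regions (19.5%) shared, but the ratio to random placement was lower, at 3.84.

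Regions of both marks overlapped in 2069 pairs with a median shared length of 1800 bp. The H3K4me3 region lay wholly inside the H3K27me3 region in 1055 pairs (51.0%) and the reverse held in 247 pairs (11.9%). The share of H3K27me3 regions that overlapped H3K4me3 was 32.5% (29.9 to 35.2%) under 2 kb and 75.4% (66.8 to 82.8%) at 20 kb or more. Broader regions have more room for an overlap, and by length H3K4me3 regions covered 28.7% of the narrowest group, 38.4% of the regions of 2 to 5 kb and 16.3% of the broadest group. Among shared H3K4me3 regions, H3K4me3 and H3K27me3 densities tended in opposite directions, with rho -0.377 (-0.419 to -0.339) across 2025 regions, which are not independent replicates. These are whole-embryo libraries, so overlap of regions does not say that both marks sit in the same cells.

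The widest H3K27me3 regions were broad domains within which H3K4me3 regions were also called. All 10 of the widest overlapped H3K4me3, with 55 H3K4me3 regions in 743.65 kb, and together they held 12.3% of the H3K27me3 reads inside regions. Over their whole length these domains had 1.11 to 7.83 RPKM of H3K4me3. Whether H3K27me3 chromatin carried over into the H3K4me3 library contributed to these H3K4me3 calls was not tested. The widest, on scaffold 56 at 1357451 to 1489100, had 75.3 RPKM of H3K27me3 and 14 H3K4me3 regions covering 36.9% of its length. The 103.8-kb region on scaffold 226 at 331601 to 435400 had the highest H3K27me3 density of the 10, 84.4 RPKM, with 11 H3K4me3 regions over 35.7% of its length. On scaffold 334 at 498701 to 574650, 10 H3K4me3 regions covered 48.3% of a 75.95-kb region. Scaffold 163 at 555251 to 647000 held only 3 H3K4me3 regions in 91.75 kb, and scaffold 73 at 291101 to 355950 held 1 in 64.85 kb, covering 2.24% of it. RNA density inside the 10 domains ran from 0.0154 RPKM on scaffold 37 at 1827951 to 1886950 to 5.85 RPKM on scaffold 261 at 923251 to 976100, where RNAPII was also highest, at 4.56 RPKM.

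**Figure D1:**
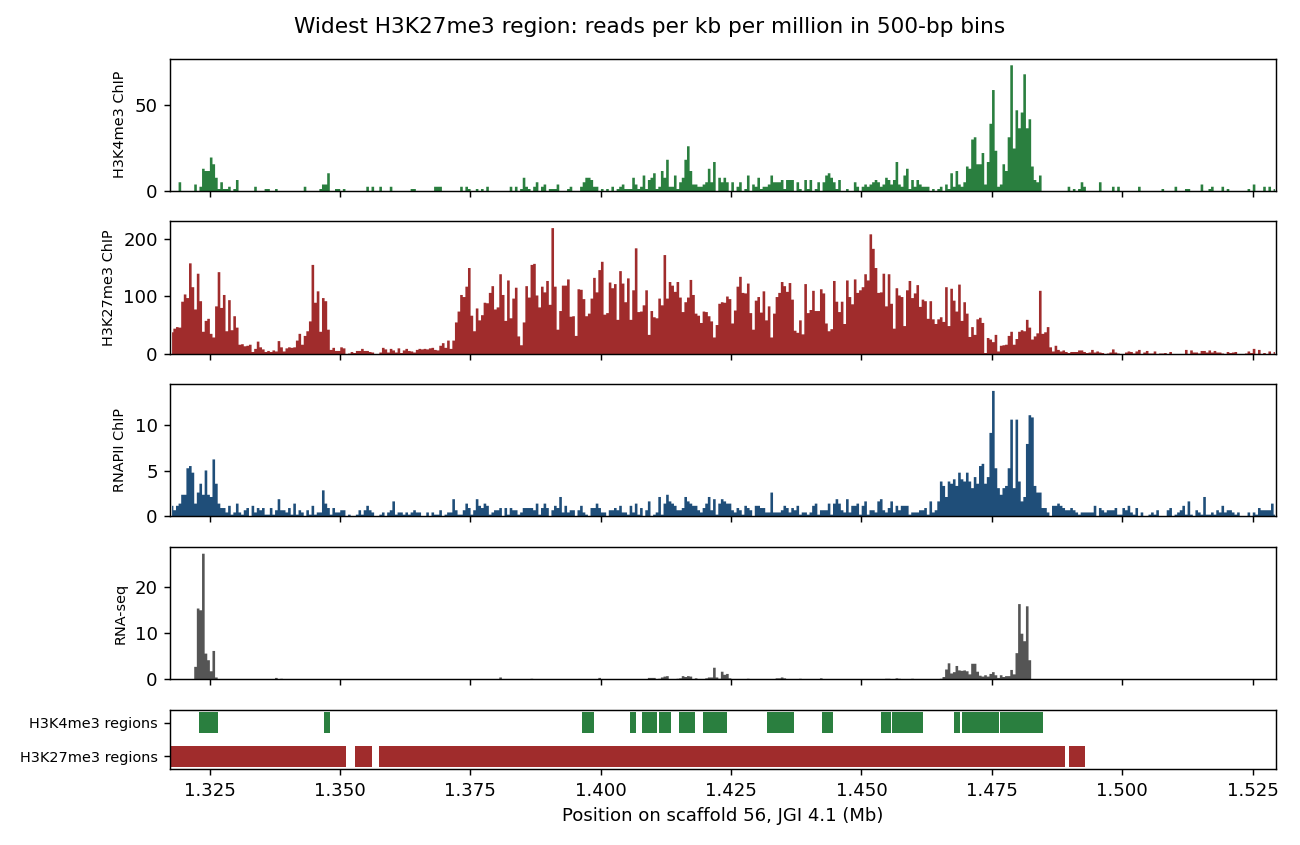
Read density (RPKM) in 500-bp bins of the 4 libraries along scaffold 56 (position in Mb on the x axis), with the deposited H3K4me3 and H3K27me3 regions as bars. H3K27me3 spans the 131.65-kb region from 1357451 to 1489100, and 14 H3K4me3 regions lie within it.

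Of the 10 widest H3K4me3 regions, which measured 11.4 to 19.6 kb, 7 overlapped H3K27me3. Of all 18 H3K4me3 regions of at least 10 kb, 9 did, and in the widest of 5 equal groups of H3K4me3 regions the share was 18.9%, against 16.5% of the whole list. The widest, on scaffold 33 at 1097451 to 1117050, was also the longest overlap of the marks, with 25.7 RPKM of H3K4me3, 15.7 RPKM of H3K27me3, 21.0 RPKM of RNAPII and 23.8 RPKM of RNA. The overlap on scaffold 44 at 2617701 to 2630000 had the same pattern, with 41.6 RPKM of H3K27me3 beside 20.0 RPKM of RNAPII and 15.1 RPKM of RNA. A 15.15-kb overlap on scaffold 35 at 1541301 to 1556450 carried 17 RPKM of H3K4me3 and 28.9 RPKM of H3K27me3 but only 4.24 RPKM of RNAPII and 0.0947 RPKM of RNA. The 3 unshared regions among the 10 widest, on scaffolds 30, 130 and 31, had 5.12, 19.0 and 21.9 RPKM of RNAPII.

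Reads of each mark were then counted in regions called for the other mark alone, to see what the region lists leave out. H3K27me3-only regions held 3.12 times the background density of H3K4me3 (3.06 to 3.19, exact Poisson, 1738 regions), against 60.8 times in the 10256 H3K4me3-only regions. H3K4me3-only regions held 2.93 times the background density of H3K27me3 (2.91 to 2.95), against 49.2 times in H3K27me3-only regions. Shared H3K4me3 regions had 51.4 times the background of H3K4me3 and 46.7 times that of H3K27me3. In median density, shared H3K4me3 regions carried 11.8 RPKM of H3K4me3 (11.4 to 12.2) and H3K4me3-only regions 14.9 RPKM (14.7 to 15.2). The background is all sequence outside both lists, gaps and unmappable sequence included, so folds over it are raised by an unknown factor. Against local background 5 to 20 kb away, the marks in their own regions were lower, at 37.9 times for H3K4me3 in H3K4me3-only, 27.1 times for H3K27me3 in H3K27me3-only and 34.6 and 27.4 times for H3K4me3 and H3K27me3 in shared H3K4me3 regions.

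**Figure D2:**
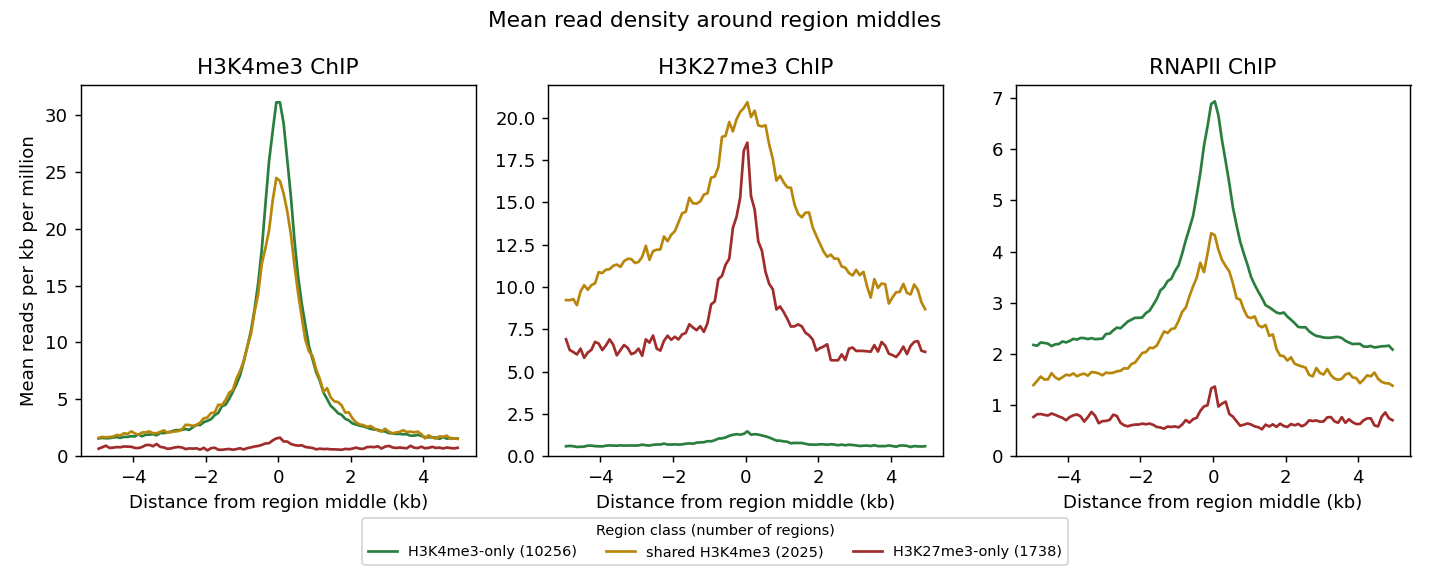
Mean read density (RPKM) in 100-bp bins within 5 kb of region middles, for H3K4me3, H3K27me3 and RNAPII, in 10256 H3K4me3-only, 2025 shared H3K4me3 and 1738 H3K27me3-only regions. Within 500 bp of the middle, RNAPII averaged 6.09 in H3K4me3-only, 3.87 in shared and 1.02 in H3K27me3-only regions.

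RNA was compared between the chromatin classes to ask how each mark relates to transcript level. By medians, RNA was highest around H3K4me3-only regions, lower around shared regions and lowest around H3K27me3-only regions. Median RNA density in the region and 5 kb either side was 0.444 RPKM (0.419 to 0.470) for 10256 H3K4me3-only regions, 0.116 RPKM (0.104 to 0.135) for 2025 shared H3K4me3 regions and 0.0128 RPKM (0.0120 to 0.0151) for 1738 H3K27me3-only regions, or 0.456, 0.120 and 0.0143 RPKM with flanks ending at scaffold ends. At least 10 RNA reads were found around 85.5% (84.9 to 86.2%), 70.7% (68.7 to 72.7%) and 34.2% (32 to 36.5%) of them. The shared and H3K27me3-only medians lay below those of all 10000 random sets of as many regions, which centred on 0.273 and 0.274 RPKM, and the H3K4me3-only median lay above those of all its random sets. Most pooled regions were H3K4me3-only, so that last place follows from the lower medians of the other classes.

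On a log2 scale with a pseudocount of 0.1 RPKM, mean RNA was 0.98 higher in H3K4me3-only than in shared regions (0.89 to 1.08) and 1.11 higher in shared than in H3K27me3-only regions (1.00 to 1.21). The sizes of these steps depended on the pseudocount and on the region threshold: with a pseudocount of 1 they were 0.44 and 0.40, and in the upper 50% of each list 0.60 and 1.60. Some regions of both classes had very high RNA. With 5 kb either side, the 5 highest H3K4me3-only regions, on scaffolds 73, 268, 56, 161 and 587, had 371 to 593 RPKM. The 5 highest shared regions had 78.1 to 313 RPKM by that measure. Mean RNA within 500 bp of the region middle was 5.18 RPKM in H3K4me3-only and 5.11 RPKM in shared regions. Without the highest region of each class it was 5.01 and 4.16 RPKM, and without the 10 highest 4.14 and 2.21 RPKM. Those 10 are a larger share of the 2025 shared than of the 10256 H3K4me3-only regions. The shared region with the highest RNA, on scaffold 43 at 2618251 to 2623500, had 908 RPKM of RNA inside it, with 56.4 RPKM of H3K4me3, 77.7 RPKM of H3K27me3 and 20.4 RPKM of RNAPII. Next in rank, shared regions on scaffolds 469, 18215, 293 and 96 had 0.383, 747, 253 and 532 RPKM of RNA inside them. Their H3K27me3 was 5.41, 299, 1.78 and 210 RPKM. Regions on scaffolds 43, 18215 and 96 were high in H3K4me3, H3K27me3 and RNAPII at once, against shared medians of 11.8, 8.05 and 1.49 RPKM. Input DNA was not analysed here, so strong marking there cannot be told apart from a property of the sequence itself. The H3K27me3-only region ranked first by RNA, at 1 to 500 of scaffold 7193, spanned the whole known length of its scaffold and had 1346 RPKM of RNA. Of those ranked 2 to 5, the regions on scaffolds 1095, 48, 12 and 481 had 0.0342, 0, 0.136 and 0.693 RPKM inside the region itself and between 18.4 and 32 RPKM when 5 kb either side was added.

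**Figure D3:**
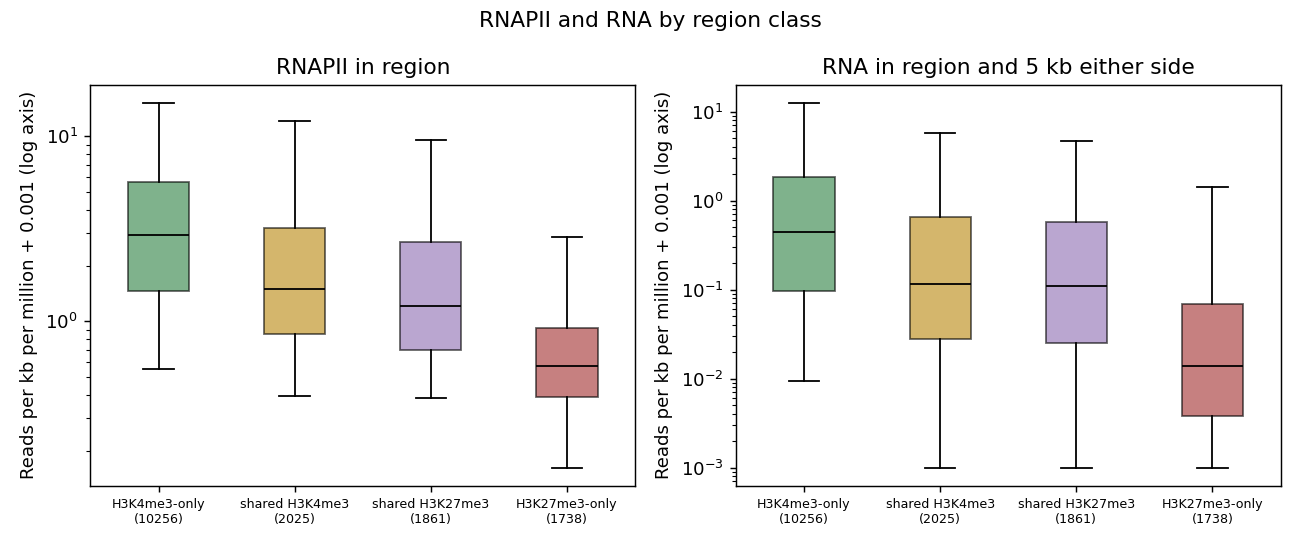
RNAPII density in the region (left) and RNA density in the region and 5 kb either side (right), in RPKM plus 0.001 on log axes, for 4 region classes with the number of regions in parentheses. Boxes span the quartiles with the median as a line, and whiskers reach from the 5% to the 95% quantile: RNAPII medians go from 2.93 in H3K4me3-only to 0.576 in H3K27me3-only regions.

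RNAPII followed the same order of classes. Median RNAPII density was 2.93 RPKM (2.85 to 3.01) in H3K4me3-only regions, 1.49 RPKM (1.42 to 1.58) in shared H3K4me3 regions and 0.576 RPKM (0.556 to 0.592) in H3K27me3-only regions, the last being 1.42 times background (1.41 to 1.44) in total reads. The order also held when regions were matched on RNA in the region and 5 kb either side. RNAPII was counted in the region alone, so the matched RNA may come from neighbouring sequence. Lower RNAPII at equal transcription of the region itself is therefore not shown. Against 10000 random sets matched on 10 equal groups of RNA density, shared regions had 0.821 and H3K27me3-only regions 0.623 of the random median RNAPII, below every set, and H3K4me3-only regions 1.09 of it, above every set. The place of H3K4me3-only regions follows from that of the others, since most pooled regions were H3K4me3-only. The gap between H3K4me3-only and shared regions was not present at all RNA levels, and intervals of these classes overlapped in level groups 1, 8, 9 and 10 of 10. In the middle of the RNA range (level group 5 of 10), RNAPII medians were 2.65 RPKM (2.52 to 2.80) and 1.87 RPKM (1.55 to 2.19). In the group with the most RNA they were 8.35 RPKM (7.97 to 8.79, 1262 regions) and 11.0 RPKM (7.59 to 14.1, 116 regions), whose intervals overlap. H3K27me3-only regions in that top group had 1.93 RPKM (0.927 to 4.0, 23 regions).

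Of the 10 H3K27me3 regions with the highest RNAPII, 6 lay on scaffolds under 10 kb long, such as scaffold 18215 at 1 to 3300, where H3K4me3, H3K27me3 and RNAPII reached 145, 299 and 79.4 RPKM together. The remaining 4 lay on scaffolds 43, 124, 12 and 62, which are long. The highest of them, on scaffold 43 at 2619251 to 2621200, lies inside the shared H3K4me3 region with the highest RNA. It was also high in all libraries, with 128 RPKM of H3K4me3, 208 RPKM of H3K27me3, 52.3 RPKM of RNAPII and 2442 RPKM of RNA. Without input DNA, strong marking at such regions cannot be told apart from a property of the sequence itself. Scaffold 124 at 149751 to 151300 had 46.1 RPKM of RNAPII with 45.2 RPKM of H3K4me3 and 5.52 RPKM of H3K27me3, and scaffold 12 at 4635301 to 4644250 had 38.1 RPKM of RNAPII and 75.2 RPKM of RNA.

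Across the 12281 H3K4me3 regions, RNAPII and RNA were higher where H3K4me3 was higher and lower where H3K27me3 was higher. Spearman rho was 0.421 (0.407 to 0.437) for H3K4me3 with RNAPII, 0.312 (0.297 to 0.333) for H3K4me3 with RNA, -0.204 (-0.222 to -0.188) for H3K27me3 with RNAPII and -0.229 (-0.246 to -0.212) for H3K27me3 with RNA. RNAPII and RNA had the highest rho, 0.600 (0.590 to 0.613). Wide H3K4me3 regions carried more RNAPII, with medians of 1.49 RPKM in the narrowest of 5 equal groups and 5.90 RPKM in the widest. These values describe regions, which are not independent replicates, and no p-value is given. Among the 10206 regions with at least 10 RNA reads, rho of H3K4me3 with RNA was lower, at 0.192.

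Grouping H3K4me3 regions into 5 equal groups by RNA gave the same relations in steps. From the lowest to the highest RNA group, the share of regions that also overlapped H3K27me3 went from 28.2% (26.4 to 30.0%) to 9.08% (7.97 to 10.3%). Median RNAPII went from 1.03 to 6.52 RPKM and median H3K4me3 from 9.55 to 18.8 RPKM. Median H3K27me3 went from 1.86 to 0.852 RPKM. In the 10256 H3K4me3-only regions median H3K27me3 was 0.966 RPKM, and 10.7% of them had no H3K27me3 reads. These medians, and rho of H3K27me3 across all H3K4me3 regions, therefore include many low counts in regions not called for H3K27me3. Inside shared regions the relation of H3K27me3 with RNA was near 0, with rho -0.0601 (-0.102 to -0.0162), and across all 3599 H3K27me3 regions it was 0.0639 (0.0307 to 0.0963). Both changed sign among regions with at least 10 RNA reads, to 0.0349 over 1432 shared and -0.0207 over 1924 H3K27me3 regions, so no direction is drawn from them.

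The genome was also read from the RNA side, in 138212 windows of 10 kb. H3K4me3 regions were found in 0.966% (0.889 to 1.05%) of 59611 windows without RNA reads, in 24.5% of windows with 10 to 99 reads, in 37.0% (35.4 to 38.6%) of windows with 1000 to under 10000 reads and in 59.4% (53.0 to 65.6%) of 244 windows with 10000 or more. H3K27me3 regions were found in 1.39% (1.30 to 1.49%) of windows without RNA, in 6.14% (5.81 to 6.49%) of those with 10 to 99 reads and in 4.0% (3.38 to 4.70%) of those with 1000 to under 10000. H3K27me3 was most frequent at low, not zero, RNA, and 845 of the 1192 windows with H3K27me3 at 10 to 99 reads also held H3K4me3. Without RNA, 178 of the 829 windows with H3K27me3 did, so much of the rise was in windows that held both marks. Windows without RNA also take in gaps and unmappable sequence, where no region can be called. Their shares are lowered by an unknown factor.

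**Figure D4:**
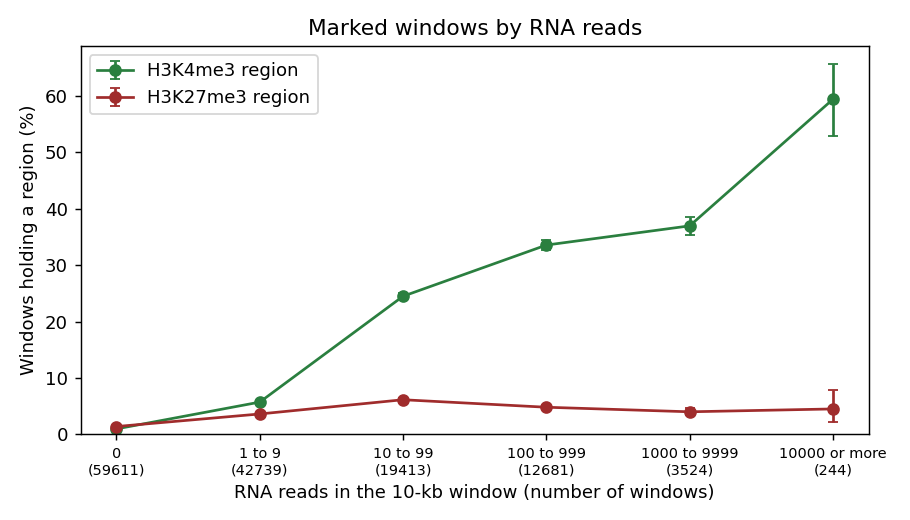
Percentage of 10-kb windows that hold an H3K4me3 or an H3K27me3 region, by number of RNA reads in the window, with 95% exact Clopper-Pearson intervals and the number of windows in parentheses. H3K4me3 goes from 0.966% without RNA to 59.4% at 10000 reads or more, while H3K27me3 is highest at 10 to 99 reads (6.14%).

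The deposited expression table gave RNA per gene model. Of 26890 models, 12641 (47.0%) had at least 10 reads and 9686 (36.0%) had none, and 425 models held 50% of the 15683896 reads. Because model identifiers carry a scaffold number, models that are alone on their scaffold could be classed by the regions on it. At least 10 reads were found for 66.4% of the 122 models whose scaffold held H3K4me3 only (57.3 to 74.7%), for 58.8% of 17 with both marks (32.9 to 81.6%), for 37.1% of 35 with H3K27me3 only (21.5 to 55.1%) and for 18.9% of 1601 with neither (17 to 20.9%). The median levels of all 3 marked classes lay high among 10000 random sets of as many single models, at percentile 100 for H3K4me3 only, 99.4 for H3K27me3 only and 98.4 for both. Most single models were the 1601 unmarked ones, whose median level was 0, so these percentiles mainly set marked against unmarked models. Unmarked models also lay on shorter scaffolds, with a median of 7.25 kb. The medians were 15.6 kb for H3K4me3 only, 12.3 kb for H3K27me3 only and 19.9 kb for both. On scaffolds of at least 10 kb the percentiles were 100, 80.9 and 84.1. The mean log2 difference between H3K4me3-only and H3K27me3-only models was 0.81, with an interval of -0.46 to 1.94 that includes 0, and became 2.02 on scaffolds of at least 10 kb.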

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

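This part takes up 2 signals that the comparisons did not measure, the spacing of read starts and RNA far from H3K4me3. The second comes from the same windows, RNA reads and H3K4me3 regions as the report. The limits of each test were set before its result was seen.

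In the H3K4me3 library 34.8% of read starts had a partner exactly 1 bp on, against 5.43% at 2 bp, and in the H3K27me3 library 31.6% against 10.8%, whereas RNAPII had 6.64% and 6.55%. Dense reads at enriched sites are argued against, because the excess at 1 bp was no smaller outside the regions: outside over inside was 1.05 for H3K4me3 and 1.27 for H3K27me3. That the same molecule may have been entered in both places stays open, since the H3K4me3 ratio lay within the range set for it and the H3K27me3 ratio just beyond. No biological explanation was tested. Counting such pairs as 1 read left 67.0% of H3K4me3 and 72.0% of H3K27me3 reads, so if the pairs are copies, counting intervals for both marks are too narrow.

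Of 3768 windows of 10 kb with at least 1000 RNA reads, 206 (5.47%) lay over 50 kb from any H3K4me3 region or on a scaffold without one. The latter numbered 43, and for them no distance could be measured. Of the 206 windows, 1 held an H3K27me3 region. Reads piled on single positions are argued against, since the most frequent start held a median of 1.43% of a window's reads. Promoters cut off at scaffold ends may account for part, as 33.0% of these windows lay within 50 kb of an end against 13.1% of RNA-matched windows near H3K4me3 (2.52 times), but most did not. Matched windows could lie only on scaffolds with an H3K4me3 region, so part of this excess may follow from how far windows were defined. RNA present with little ongoing transcription, as for stored maternal RNA, is a hypothesis that stays open. Median RNAPII was 0.485 of that in the matched windows (0.426 to 0.553), 127.5 reads against 263, and the limit of 0.5 lies inside that interval. The comparison cannot decide the question, because the matched windows were chosen near H3K4me3 regions, where RNAPII is high. Some deficit in windows chosen away from such regions follows from that choice. RNAPII in windows over 50 kb from H3K4me3 without RNA had a median of 22 reads, a level that only 12 of the 206 windows did not exceed.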

How the results depend on the processing

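Of 87 alternative values for 31 results, 35 stayed within the interval of the reported value or within 1.5 times the reported count, 50 moved beyond it on the same side and 2 changed sign. These 2 were rho of H3K27me3 with RNA among regions with at least 10 RNA reads, 0.0349 in shared H3K4me3 and -0.0207 in all H3K27me3 regions. The share of H3K27me3 regions that overlapped H3K4me3, 51.7%, was 49.5% when 0.5 of the narrower region had to overlap, so it lay on either side of 50%. The 1-bp collapse, the local background, other flanks and middles, flanks ending at scaffold ends, 20-kb windows, scaffolds of at least 10 kb and RNA entries per kb of scaffold were chosen after seeing the data, and so was the use of the RNA floor, itself set before, on rho within shared, H3K27me3 and H3K27me3-only regions. Apart from fewer regions or reads entering by construction, the cause of these moves was not tested.

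In the upper 50% of each list, 352 H3K4me3 and 351 H3K27me3 regions were shared, 3.84 times random placement, and mean log2 RNA was 0.60 higher in H3K4me3-only than shared regions and 1.60 higher in shared than H3K27me3-only regions. With a pseudocount of 0.01 these RNA differences were 1.42 and 2.08, with 1 they were 0.44 and 0.40, with at least 10 RNA reads 0.72 and 0.54, and in the region alone 0.74 and 1.46. RNAPII within 500 bp of the middle gave log2 differences of 0.84 and 1.47, and within 1 kb 1.48 for shared minus H3K27me3-only.

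With 1 read per start, 55.2% of H3K4me3 and 38.8% of H3K27me3 reads lay in their own regions, and folds over background were 59.8 for H3K4me3 in H3K4me3-only, 47.5 for H3K27me3 in H3K27me3-only, 50.8 and 45 for H3K4me3 and H3K27me3 in shared H3K4me3 and 1.40 for RNAPII in H3K27me3-only regions. The 1-bp collapse gave 54.0% and 35.7%, folds of 57.0, 41.8, 48.4, 39.8 and 1.38 in the same order, and 2.87 for H3K27me3 in H3K4me3-only regions. The local background gave 37.9, 27.1, 34.6, 27.4 and 1.37 in that order, and with it H3K4me3 in H3K27me3-only regions was 2.76 times and H3K27me3 in H3K4me3-only regions 2.39 times background. The ratio of H3K4me3 to H3K27me3 density in overlaps went from 0.681 to 0.902 when scaled to reads outside both lists.

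Among H3K4me3 regions with at least 10 RNA reads, rho was 0.365 for H3K4me3 with RNAPII, 0.192 for H3K4me3 with RNA, -0.162 for H3K27me3 with RNAPII, -0.192 for H3K27me3 with RNA and 0.489 for RNAPII with RNA; among such H3K27me3 regions it was 0.489 for width with H3K27me3. H3K4me3 regions lay in 55.1% of 20-kb windows with 1000 to under 10000 RNA reads. On scaffolds of at least 10 kb, 77.0% of H3K4me3-only and 25% of unmarked single models had at least 10 reads, and the log2 difference between H3K4me3-only and H3K27me3-only models was 2.02, or 1.97 from RNA entries per kb of scaffold.

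Windows around gene 5′ ends, H3K27me3 at 5′ ends alone and the alternatives for gene lists were not run, since genes could not be placed. H3K4me3 depth, a median of 4 reads per 10 kb, limits what can be said of weakly marked regions.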

Other observations

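Among the tests in this part, the one on mappable sequence, and the rho and medians set beside the one on carry-over, were chosen after the result was seen.

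H3K27me3 regions often lie close together. Joining regions less than 2 kb apart turned the 3599 regions into 3083 domains, of which 159 measured at least 20 kb and 17 at least 50 kb. The broadest, made of 5 regions on scaffold 56 at 1306451 to 1492900, measured 186.45 kb and contains the widest single region.

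Very high density of all 3 ChIP libraries was found mostly on short scaffolds. Whether the sequence itself raised all of them was not tested, as input DNA was not analysed here. H3K4me3 regions over 30 RPKM in all 3 ChIP libraries numbered 6, of which 83.3% lay on scaffolds under 10 kb, with medians of 99.1 RPKM of H3K4me3, 241 RPKM of H3K27me3 and 66.8 RPKM of RNAPII. Shared H3K4me3 regions on such scaffolds numbered 46 (2.27%) and H3K27me3-only regions 152 (8.75%).

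The gene model with the most RNA, fgenesh1_Sanger_cdna.C_scaffold_7193000001, had 73414 reads in the expression table, while 14073 RNA entries lay on its scaffold. Scaffold 7193 at 1 to 500 was also ranked first by RNA, with 5 kb either side, among H3K27me3-only regions. The 10 models with the most reads held 7.53% of all reads on models.

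RNAPII was high in a few windows away from H3K4me3 regions. On scaffold 782 at 270001 to 280000, 6.5 kb from the nearest H3K4me3 region, 2666 RNAPII reads (2566 to 2769) came with 77 RNA reads. This window also held 29 H3K4me3 reads, above the median of 4 per 10-kb window. On scaffold 411 at 650001 to 660000 there were 4326 RNAPII reads (4198 to 4457) with 14385 RNA reads and 19 H3K4me3 reads.

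A hypothesis is that regions called for H3K27me3 alone may carry H3K4me3 below the level at which regions were called, since H3K4me3 reads there were 3.12 times background. More mappable sequence stays open as part of the cause: in 424 H3K27me3-only regions without RNA, set against 58384 windows without RNA outside both lists, RNAPII was 2.07 times (1.92 to 2.25) and H3K4me3 4.1 times higher (3.68 to 4.52), a ratio of 0.505 (0.452 to 0.566), and RNAPII is only a stand-in for input DNA, which was not analysed here. Spill from nearby H3K4me3 regions is argued against by the 1379 regions over 10 kb from any, with 3.05 times background (2.98 to 3.13). For carry-over of H3K27me3 chromatin, 4 equal groups by H3K27me3 density were compared. The top group (median 17.9 RPKM) had 1.02 times the H3K4me3 density of the bottom group (0.962 to 1.09), whose median H3K27me3 was 4.94 RPKM. H3K4me3 thus did not rise in proportion to H3K27me3 within these regions. The ratio cannot exclude carry-over, because regions that it had lifted to an H3K4me3 call would be missing here. Of H3K27me3 regions of 20 kb or more, the most densely marked, 75.4% were shared. The groups also differed in median width, 3900 bp in the top and 1800 bp in the bottom group. Carry-over stays open also because H3K27me3 and H3K4me3 had a rho of 0.0995 (0.0553 to 0.142) over the 1738 regions. Median H3K4me3 was 0.872 RPKM (0.779 to 0.980) in the top and 0.727 RPKM (0.595 to 0.844) in the bottom group.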
